A study of Mus musculus with 12 samples.

How the data were processed

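Gene expression was measured by RNA sequencing in 12 libraries of the mouse mammary tumour line 4T1, in 4 groups of 3 named by the labels: mock, MYBup, wt and lung3. Per the labels' protocols, RNA was isolated with a column kit and libraries were made with an Illumina TruSeq RNA kit. The deposited values are raw counts of reads per gene, not normalised, in a table of the whole series. Per the submitters' processing notes, STAR, edgeR and the genome build GRCm38 were used; their versions, the counting tool, the annotation and the strand setting are not given in the sources used here. The table holds 22880 features by Ensembl identifier, of which 22570 matched a symbol, 21452 are protein coding and 7336 had 0 counts in all libraries. The 2708 largest values, those with over 4 digits, are rounded to 4 significant digits in the deposited table, which can move a count by at most 0.05%. It holds 0 columns that were not used. Coordinates are those of GENCODE M21 on GRCm38, 1-based.

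Total counts were 21104811, 14117503 and 14917457 for mock replicates 1 to 3, 12170188, 13175276 and 18385271 for MYBup, 22171764, 24745660 and 20617046 for wt and 13899321, 8912989 and 14689339 for lung3. Ratios of count sums are given with exact 95% intervals, and a group without counts with a floor of 3 counts; these cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates differed by more than sampling noise, with a chi-square per gene between 2.29 and 37.3 for pairs within a group. No pair was therefore counted as 1 sample.

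Tests used R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr, all 12 libraries in 1 fit with a term per group), and adjusted p is Benjamini-Hochberg over the 11291 tested genes with a threshold of 0.05. CPM values were computed with TMM factors, and SE is the absolute log2 fold change divided by the square root of F. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists with at least 3 tested members; camera compares a list with the other genes. Mixed splits of the libraries also gave camera calls, so the preset correlation may be too low for these lists. Its estimated-correlation form and fry, which asks only whether a list's genes move one way on balance, were alternatives. A count adjusted over the list alone repeats the adjustment within the members. DESeq2 1.42.0 and limma voom were alternatives, and figures used Python 3.11.15 with matplotlib 3.10.9.

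The groups, designs, 24 lists, other settings to try and rule for named genes were fixed before the data were examined. The rule took the 8 genes with the largest rise and the 8 with the largest fall in each main comparison, 4 each way for mock against wt, among those past the threshold with an average log2 CPM of at least 3, group CPM values that do not overlap and a proper symbol. It also took the 8 opposite genes each way with the largest smaller change, up to 4 called members of each list, Myb, and Ccl2, which was included in advance because the study is known for it. 1 of the genes taken by this rule is not reported here. The lists cover chemokines and cytokines, NF-kB, interferon, MHC class I, epithelial, mesenchymal, matrix, protease, adhesion, c-Myb target, G2/M, S phase, hypoxia, cholesterol, ATF4, NRF2, TGF-beta and YAP, lung metastasis, oxidative phosphorylation and ribosomal genes and markers of 4 host cell types.

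Whether replicate numbers pair libraries was checked by correlating the deviations from group means. For lung3 and wt the same-number correlations were 0.329, 0.294 and 0.309, and those of unlike numbers lay between -0.212 and -0.093. Between MYBup and mock, libraries of unlike number reached 0.636, so values of this size do not establish pairing. The labels state no pairing, and the replicate blocks within lung3 and wt were chosen after the data were seen. Alternatives were RLE size factors, no filter, a replicate block, fits on the 6 libraries compared, DESeq2, limma voom, a 2-fold minimum and leaving out each library; those added after seeing the data are named where they are given.

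The edgeR script was checked on counts simulated from the real means and library sizes. In 11203 genes with 200 changed between MYBup and mock, it recovered 51.5% of 1.5-fold, 89.6% of 2-fold and 98.5% of 4-fold changes, with 5.36% false calls, and called 0 genes between unchanged lung3 and wt. DESeq2 had 10.4% false calls and 6 calls between the unchanged groups. On simulated data camera called the list that had been shifted and 1 other.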

Results

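RNA from 4T1 cells, a mouse mammary tumour line that spreads to the lung, was sequenced in 4 groups of 3 libraries. The mock cells carried an empty expression plasmid. The MYBup cells carried the same kind of plasmid with mouse Myb, the gene of the transcription factor c-Myb. The wt cells were untransfected, and the lung3 cells had been passaged 3 times through the lungs of mice. Per the labels, MYBup cells have a lowered and lung3 cells a raised capacity to colonise the lung. Total counts ran from 8912989 in lung3 replicate 2 to 24745660 in wt replicate 2. Of 22880 features in the count table, 11291 passed the filter on low counts and were tested. The labels do not say that the 3 libraries of a group came from separate cultures, so all p-values measure the spread between these libraries, which may be technical.

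The comparison of MYBup with mock cells asked which genes follow the level of Myb. Myb itself (ENSMUSG00000019982, chromosome 10, 21124935 to 21160984, GRCm38) stood at 40.7 ± 1.94 CPM in MYBup and 5.49 ± 1.19 CPM in mock cells (SD, n = 3), a log2 fold change of 2.89 (SE 0.15, adjusted p = 5.21e-08). Reads from the plasmid and from the cell's own gene fall into the same row. The labels do not say whether mock and MYBup cells are pools or clones, so a difference between the 2 lines cannot be separated from an effect of Myb. MYBup cells had nearly lost the transcripts of several inflammatory mediators. Genes of cholesterol synthesis fell together, and the hypoxia marker Car9 rose. In all, 3038 of 11291 genes changed, 1615 of them higher and 1423 lower in MYBup, and 613 changed at least 2-fold.

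Among the genes that met the naming rule, the largest increase was that of Rbpms, which encodes an RNA-binding protein (chromosome 8, 33782643 to 33929863), at 19.3 ± 0.609 CPM in MYBup against 0.370 ± 0.0514 in mock cells (log2 fold change 5.65, SE 0.22, adjusted p = 5.94e-09). Prom2, a membrane protein related to prominin, rose by 2.76 on the log2 scale, and the zinc transporter gene Slc39a4 by 2.70. Car9, the gene of carbonic anhydrase 9, reached 125 ± 5.18 CPM against 21.2 ± 0.716, and Ptpru, a receptor tyrosine phosphatase, 28.0 ± 2.55 against 5.77 ± 1.04. Stc2 (log2 fold change 2.33) and Sulf2 (2.26, adjusted p = 0.000772) completed the 8 genes with the largest increase. The levels in untransfected cells differed among these genes. Against wt cells, Myb, Car9 and Ptpru had log2 fold changes of 3.02, 2.71 and 2.96 in MYBup, Rbpms had 1.30 and Prom2 0.72, but Stc2 had -0.70 (adjusted p = 0.0011) and Slc39a4 0.45 (adjusted p = 0.23). Exons of Sulf2 overlap exons of Ncoa3 on the opposite strand by up to 154 bases, and the strand setting of the counting is not given, so its counts are uncertain.

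Some genes were almost silent in MYBup cells. B4galt6, a galactosyltransferase gene, had 1 count in the 3 MYBup libraries together and 1444 in mock, a ratio of 1280 with a 95% counting interval from 229 to 50400. For Ociad2 the sums were 1 and 827 counts, a ratio of 731 (131 to 28900). Epb41l4a had 4 counts against 961, the amino acid transporter gene Slc36a4 5 against 982, and the mechanosensitive channel gene Piezo2 5 against 703. Cobl, an actin nucleator gene, fell by 5.02 on the log2 scale. In wt cells these 6 genes stood at 11.99, 12.3, 18.3, 10.6, 9.87 and 16.8 CPM. They were therefore expressed in both reference groups.

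Il1a, the gene of the cytokine interleukin 1 alpha (chromosome 2, 129299610 to 129309972), fell from 60.9 ± 41.1 CPM in mock to 0.611 ± 0.195 in MYBup cells (log2 fold change -6.68, SE 0.91, adjusted p = 0.00018). Ccl2, a chemokine that attracts monocytes (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), had 2 counts over the MYBup libraries and 264 over mock, a ratio of 117 (95% counting interval 32.0 to 968, adjusted p = 0.00298; limma voom did not call it). Cxcl3 had 0 counts in MYBup and 348 in mock, at least 103-fold lower with a floor of 3 counts over the group, but it was high in mock, with 0.380 CPM in wt, and was not called against wt (adjusted p = 0.072). The neutrophil chemokine gene Cxcl5 fell by 4.05. Of 19 tested members of the chemokine and cytokine list, 10 fell, 3 rose and 6 did not pass (12 and 3 adjusted over the list alone). Of 19 NF-kB response genes, 9 fell and 1 rose (11 and 2 adjusted over the list alone), among them Lcn2 (lipocalin 2, log2 fold change -4.97, adjusted p = 0.00163; not called by limma voom), Birc3 (-0.82) and Tnfaip2 (-0.75). The camera test called both lists lower (adjusted p = 0.0136 for each), but not with an estimated correlation (adjusted p = 0.434 for each). Mock replicate 3 stood apart in these genes, with Il1a at 13.5 CPM against 84.2 and 85.0 in replicates 1 and 2, and Cxcl5 at 39.0 against 186 and 195. Against wt, the log2 fold changes in MYBup were -5.53 for Il1a, -4.66 for Ccl2 (adjusted p = 0.0478), -2.11 for Cxcl5 (adjusted p = 0.017), -1.59 for Lcn2 (adjusted p = 0.31) and 0.53 for Tnfaip2 (adjusted p = 0.0012).

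Cholesterol biosynthesis genes fell almost throughout the list. Of 21 tested members 18 fell and 0 rose, with the same numbers adjusted over the list alone. Insig1, a regulator of sterol synthesis, fell by 1.45 on the log2 scale, Idi1 by 1.23 and Cyp51 by 1.12. Hmgcs1, the gene of cytosolic HMG-CoA synthase (chromosome 13, 119690379 to 119708260), was at 61.4 ± 0.5 CPM in MYBup and 141 ± 21.5 in mock cells. All 4 were also lower in MYBup than in wt cells, with log2 fold changes of -1.22, -1.97, -1.49 and -1.59. The camera adjusted p was 1.6e-12, and 0.396 with an estimated correlation. Exons of Cyp51 overlap exons of Akap9 on the other strand.

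Hypoxia and glycolysis genes rose in 9 and fell in 2 of 23 tested members (11 and 2 adjusted over the list alone; camera adjusted p = 0.0129, and 0.268 with an estimated correlation). Car9 had the largest change, followed by Ankrd37 (0.85) and Hk2, a hexokinase gene that fell by 0.76. Pfkp (0.72) was lower in mock than in wt cells and had a log2 fold change of -0.04 in MYBup against wt. Of 24 G2/M genes 3 fell, Foxm1, Prc1 and Kif23, by 0.55, 0.35 and 0.32 (3 adjusted over the list alone; camera adjusted p = 0.0314, and 0.268 with an estimated correlation). Prc1 and Kif23 lost the call when each library was centred per chromosome. Against wt, Foxm1 and Prc1 had log2 fold changes of -0.24 and -0.42 in MYBup, but Kif23 was not called (-0.05, adjusted p = 0.549). Exons of Ankrd37, Pfkp, Foxm1 and Prc1 overlap exons of other genes, and their counts are uncertain without a known strand setting.

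The other lists were not called as sets. In the extracellular matrix list 8 of 22 members rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0621), with Ecm1 at 157 ± 15.02 CPM against 76.8 ± 9.28. Plat, the gene of tissue plasminogen activator, rose by 2.02 in a list of matrix proteases with 5 of 22 higher and 3 lower (6 and 3 adjusted over the list alone). Adhesion genes moved both ways, 5 higher and 6 lower of 20 (5 and 6 adjusted over the list alone), with Mcam up by 1.41 and Itga2 down (-1.38). Vcam1 and Spp1, members of a breast-to-lung metastasis signature with 4 higher and 6 lower of 13, had log2 fold changes of -1.14 and -1.23. Against wt, Vcam1 had -1.35 in MYBup, but Spp1 was high in mock (0.99) and was not called in MYBup (-0.24, adjusted p = 0.258). Among 18 reported c-Myb targets 2 rose and 3 fell (2 and 3 adjusted over the list alone). Gata3, a luminal transcription factor gene, rose by 0.65 and Cited2 by 0.46, whereas Myadm fell by 0.37 and lost its call in the chromosome-centred fit. Higher and lower members numbered 7 and 6 of 20 TGF-beta and YAP targets, 4 and 2 of 25 S phase genes, 3 and 7 of 21 ATF4 and unfolded protein response genes and 4 and 0 of 20 NRF2 genes. They numbered 3 and 0 of 20 interferon genes, 1 and 3 of 15 MHC class I genes, 2 and 3 of 23 epithelial genes, 3 and 2 of 12 mesenchymal genes, 3 and 1 of 25 oxidative phosphorylation genes and 4 and 0 of 32 ribosomal protein genes. Adjusted over the list alone, the numbers of the metastasis signature and of these 10 lists were the same, except for 4 higher mesenchymal genes, 1 higher NRF2 gene and 1 higher ribosomal protein gene. With the estimated correlation 0 of 21 lists passed in this comparison (2 at an unadjusted p under 0.05), while fry called 7. Other splits of the same 6 libraries gave up to 8 camera calls, against 5 for the real groups.

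**Figure D1:**
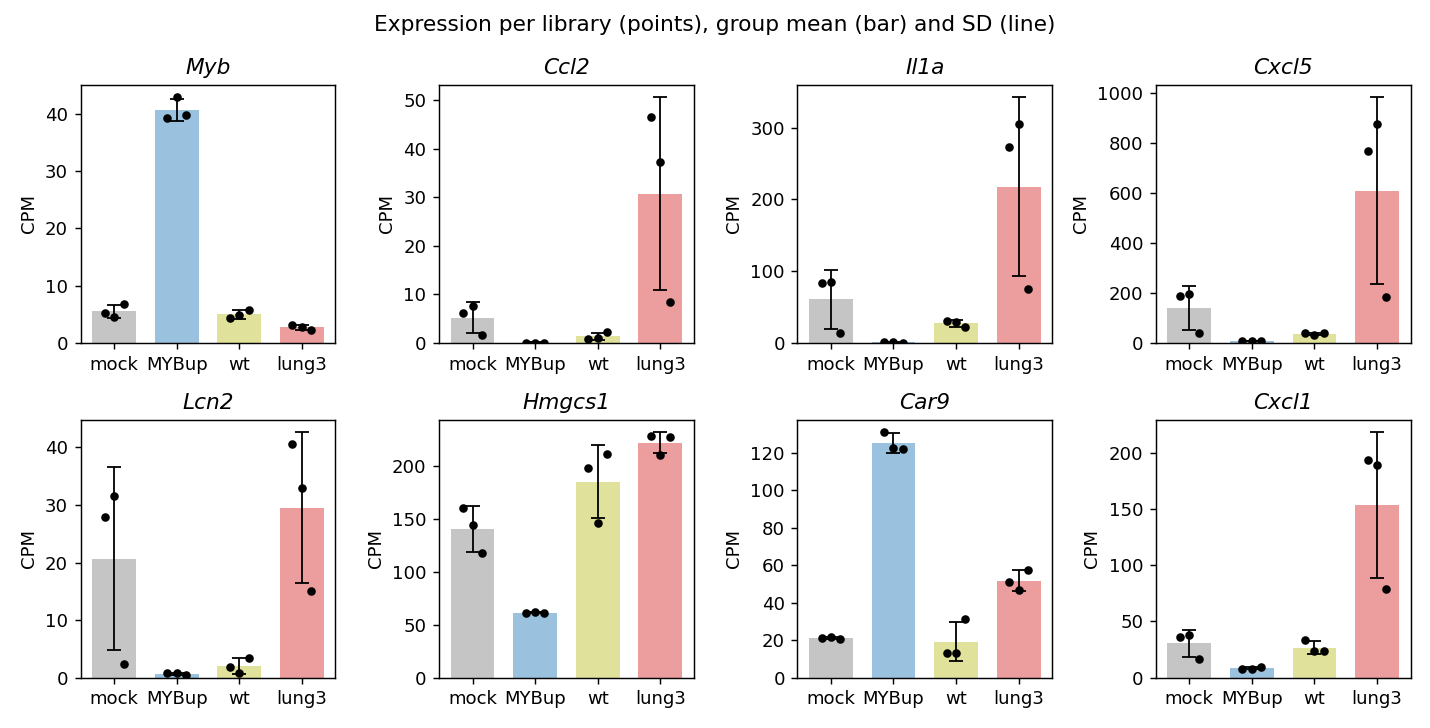
CPM of 8 genes in the 12 libraries. Points are libraries, bars group means and lines SDs (n = 3 per group, linear axes from 0). Myb is at 39.3 to 42.9 CPM in MYBup and at most 6.80 elsewhere, and Cxcl5 reaches 878 CPM in lung3 against at most 9.53 in MYBup.

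The comparison of lung3 with wt cells asked what differs after selection in the lung. The lung3 cells had higher levels of many of the inflammatory genes that were low in MYBup cells, along with Krt14 and Edn1. Myb was lower, at 2.71 ± 0.459 CPM against 4.99 ± 0.742 (log2 fold change -0.89, SE 0.19, adjusted p = 0.0158, n = 3). This call ended without wt replicate 2, lung3 replicate 2 or lung3 replicate 3, with an adjusted p of up to 0.0805. In all, 605 genes changed, 329 higher and 276 lower, 164 of them at least 2-fold. With the replicate number as a block on the 6 libraries, chosen after the data were seen, 1985 genes were called, 961 higher and 1024 lower. Whether the numbers pair these libraries is not established. Leaving out wt replicate 1, wt replicate 2 or lung3 replicate 2 lowered the count from 605 to 237, 268 and 294.

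Among the named genes Ccl2 had the largest increase, from 1.34 ± 0.720 to 30.8 ± 19.8 CPM (log2 fold change 4.52, SE 0.63, adjusted p = 0.00143). Cxcl5 rose from 36.6 ± 5.01 to 610 ± 374 CPM, Il1a from 27.3 ± 4.54 to 218 ± 125 and Cxcl1 from 26.8 ± 5.86 to 153 ± 64.9. Lcn2 (log2 fold change 3.89; limma voom did not call it), the complement gene C3 (2.93), the basal keratin gene Krt14 (2.21) and the protease inhibitor gene Slpi (1.99) were the others of the 8 genes with the largest increase, in which Il1a had 2.99 and Cxcl1 2.52. Sfrp1, a secreted Wnt antagonist, had the largest decrease of the named genes, to 3.15 ± 0.695 from 13.8 ± 1.97 CPM (log2 fold change -2.14, SE 0.18, adjusted p = 5.23e-05). Loxl3, Gpnmb, Phex, Slc36a4, Pex2, Sema6d and Nptx1 fell by 1.80, 1.67, 1.51, 1.31, 1.30, 1.25 and 1.23. Exons of Loxl3 overlap those of Htra2 on the opposite strand by up to 369 bases, so its counts are uncertain.

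Of 19 chemokine and cytokine genes 10 rose and 0 fell in lung3 cells (13 and 2 adjusted over the list alone), including Ccl20 (log2 fold change 3.49, adjusted p = 0.00273). Of 19 NF-kB genes 6 rose (12 adjusted over the list alone), including Ier3 (0.67) and Tnip1 (0.61). Lung3 replicate 3 stood apart here too, with Ccl2 at 8.46 CPM against 46.5 and 37.3, and Il1a at 74.8 against 273 and 306. The host leukocyte markers other than Cd68 summed to 1.15 CPM in lung3 and 0.584 in wt cells. TGF-beta and YAP targets rose in 7 of 20 members (7 adjusted over the list alone), with Edn1 up by 1.98, the tissue factor gene F3 by 1.02 and Ccn2 by 0.87. Of the matrix proteases and inhibitors 5 of 22 rose (9 adjusted over the list alone), including Plat (0.73, adjusted p = 0.00361). Hypoxia and glycolysis genes rose in 4 of 23 members (9 adjusted over the list alone), with Car9 at 51.8 ± 5.59 against 19.2 ± 10.3 CPM, P4ha2 up by 1.05 and Ndrg1 by 0.61.

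The camera test called 7 lists higher in lung3 cells. Adjusted p was 1.34e-07 for chemokines, 2.81e-06 for NF-kB, 4.84e-05 for hypoxia, 0.00111 for TGF-beta and YAP targets and 0.00808 for proteases. For these 5 the adjusted p was 0.059 with an estimated correlation, and the protease list also lost its call without the low-count filter. Interferon genes (3 of 20 higher, 3 adjusted over the list alone; adjusted p = 0.000588) and cholesterol genes (1 of 21 higher, 2 adjusted over the list alone; adjusted p = 0.00808) were also called, with adjusted p of 0.859 and 0.88 with an estimated correlation and 0.421 and 0.506 with fry. The interferon call ended without lung3 replicate 3, and the cholesterol call without that library or wt replicate 2, with adjusted p of up to 0.288 and 0.658. With the estimated correlation 0 of 21 lists passed (5 at an unadjusted p under 0.05), and fry called 6. Up to 11 lists were called in other splits of the 6 libraries, and 12 without wt replicate 3. The replicate block within these groups left the same 7 lists called. With it, fry also called the interferon list (adjusted p = 0.000686) but not the cholesterol list (0.282). The c-Myb targets were called higher in lung3 by fry both with it (0.0336) and without it (0.0363). With the block and an estimated correlation the adjusted p was 0.0502 for interferon, 0.766 for cholesterol and 0.0599 to 0.09 for the other 5. In the other lists, 2 epithelial genes rose and 1 fell (4 and 3 adjusted over the list alone), as did 1 and 1 mesenchymal genes (2 and 1), 2 and 0 matrix genes (3 and 0), 1 and 0 adhesion genes (1 and 0), 2 and 1 reported c-Myb targets (4 and 2), 0 and 1 ATF4 genes (0 and 1) and 2 and 0 genes of the metastasis signature (4 and 2). The edgeR test called 0 of 24 G2/M, 0 of 25 S phase, 0 of 15 MHC class I, 0 of 20 NRF2, 0 of 25 oxidative phosphorylation and 0 of 32 ribosomal protein genes.

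**Figure D2:**
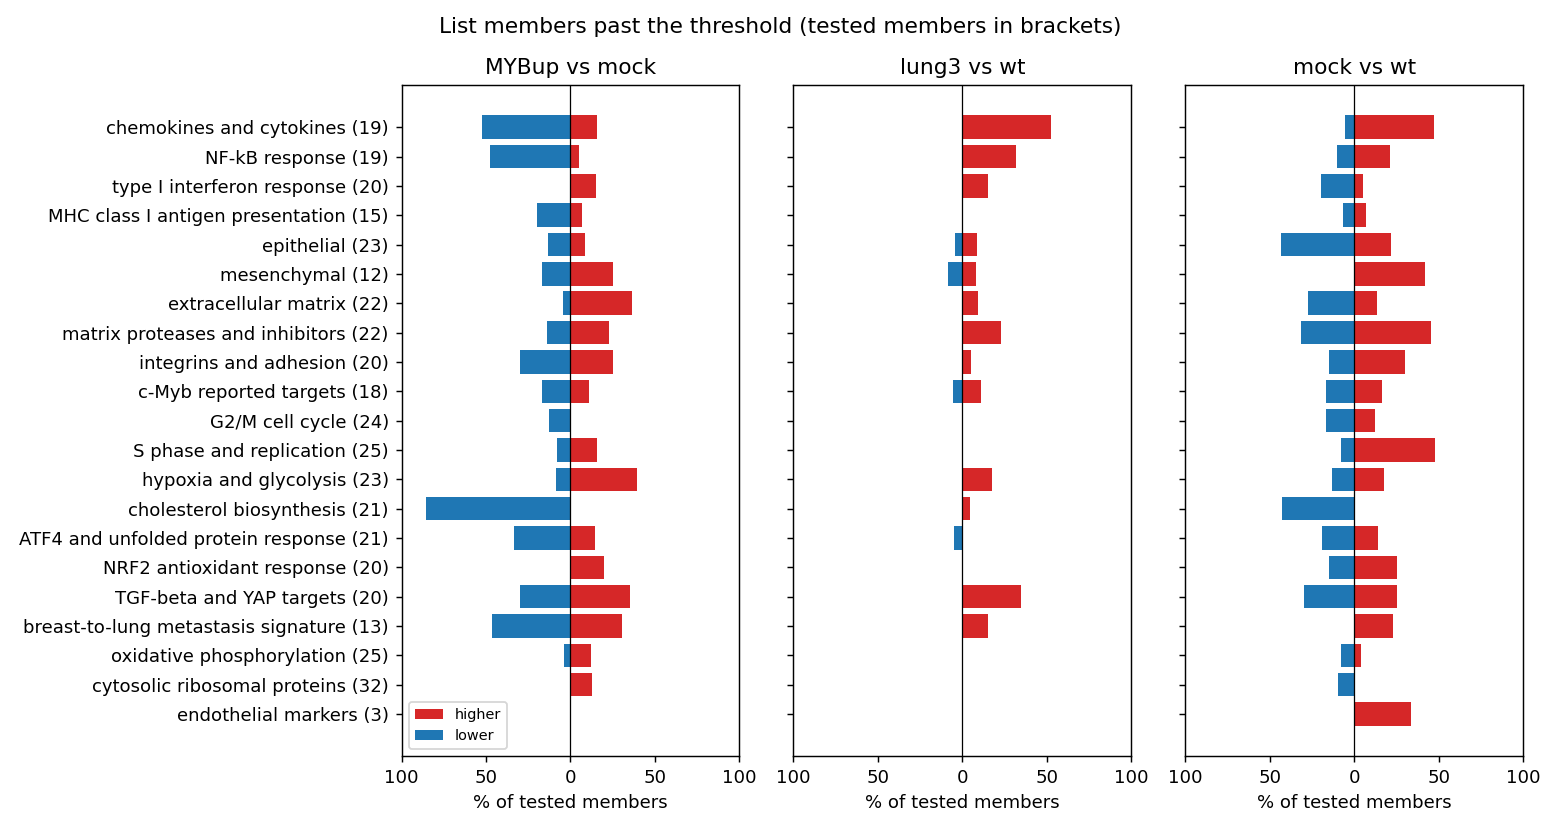
Percentage of the tested members of each list with an adjusted p under 0.05, higher (red, right) or lower (blue, left), in 3 comparisons. In MYBup against mock 18 of 21 cholesterol genes were lower, and in lung3 against wt 10 of 19 chemokine and cytokine genes were higher and 0 lower.

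The study searched for genes that move in opposite directions in the 2 comparisons, which share no library. The genes lower in MYBup and higher in lung3 were led by Ccl2, Cxcl5, Lcn2, Il1a, C3, Cxcl1, Ly6e and Zc3h12a. C3 stood at 5.25 ± 0.258 CPM in MYBup, 52.0 ± 29.3 in mock, 12.7 ± 10.7 in wt and 96.5 ± 11.7 in lung3 cells. Ly6e, a surface protein gene, was at 0.206 ± 0.0775, 1.99 ± 0.702, 11.3 ± 4.46 and 40.3 ± 16.6 CPM in that order. Zc3h12a, whose product degrades inflammatory mRNAs, had log2 fold changes of -1.67 and 1.79. Its call in lung3 ended without wt replicate 2 (adjusted p = 0.0541). The reverse group, higher in MYBup and lower in lung3, was led by Prom2 (log2 fold changes 2.76 and -1.004), the carbonyl reductase gene Cbr1 (1.56 and -0.99), Myb (2.89 and -0.89), Spsb4 (0.68 and -0.79), Selenom (0.89 and -0.65), Pik3r2 (0.56 and -0.57), Evi2a (0.53 and -0.60) and Gata3 (0.65 and -0.53). In lung3, the calls of Prom2, Cbr1, Myb, Spsb4, Selenom and Pik3r2 each ended without some library, always including wt replicate 1, wt replicate 2 or lung3 replicate 2, with adjusted p of up to 0.131. That of Cbr1 also ended in the fit on 6 libraries (adjusted p = 0.0521), that of Pik3r2 when centred per chromosome (0.0508) and that of Selenom without mock replicate 3 and lung3 replicate 3 together (0.0598). Spsb4 also lost its call in MYBup without MYBup replicate 2 or 3 (adjusted p up to 0.0793). Against wt, C3 (log2 fold change -1.27, adjusted p = 0.0986), Lcn2 (-1.59, 0.307), Spsb4 (0.14, 0.557) and Pik3r2 (0.14, 0.354) were not called in MYBup. The other named genes of both groups were called against wt in the same direction as against mock. Exons of Gata3 share up to 77 bases with the model 9230102O04Rik and those of Evi2a 221 bases with Evi2.

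In numbers, 96 genes were lower in MYBup and higher in lung3, against 41.5 for independent lists, and 67 were higher in MYBup and lower in lung3, against 39.5. Same-direction genes numbered 61 higher in both (47.1 for independent lists) and 60 lower in both (34.8), among them Car9 and Krt14 (higher) and Slc36a4 (lower). Krt14 was low in mock (log2 fold change -2.04 against wt) and was not called in MYBup against wt (0.15, adjusted p = 0.732). Among the 284 genes changed in both comparisons 163 thus moved apart and 121 together (Fisher's exact test, two-sided, odds ratio 0.57, p = 0.0227; genes are not independent replicates). At least 2-fold in both, 34 were lower and then higher, 10 the reverse, and 28 moved together. Leaving out the 4056 genes that differed between mock and wt left 38, 34 and 41. With the block on the 6 lung3 and wt libraries the 3 numbers were 197, 200 and 264, against 120, 143 and 262 for independent lists, so the genes moving together were then no more than expected. None of these numbers for independent lists allows for shifts of whole chromosomes, and the overlaps were not recounted with each library centred per chromosome. Of the genes called on chromosome 8, 228 were higher and 34 lower in MYBup against mock, and 3 and 30 in lung3 against wt. On chromosome 3 the numbers were 188 and 21, and 26 and 11. Such shifts can add opposite genes as well as genes moving together. In refits without wt replicate 1 or 2 there were 41 and 37 genes in place of the 96. Without mock replicate 1, MYBup replicate 2, MYBup replicate 3, lung3 replicate 1 or lung3 replicate 2 there were 61, 61, 58, 60 and 55. For the 67 the same 7 libraries gave 19, 28, 43, 41, 39, 44 and 36, and the 121 became 54, 58, 74, 80, 73, 83 and 62. Of the 19 chemokine and cytokine genes 7 were among the 96, against 0.162 by chance (Fisher's exact test, one-sided, adjusted p = 1e-08 over the lists and 4 patterns), and 3 of 19 NF-kB genes were (adjusted p = 0.011). This test also treats genes as independent. Its chance number is taken over all tested genes, although 10 of the 19 chemokine and cytokine genes were lower in MYBup and 10 higher in lung3. For the NF-kB genes these numbers were 9 and 6 of 19. The test therefore counts these separate shifts again, and it cannot show that the same members moved apart more often than the shifts give. The chemokine and cytokine genes had an estimated correlation of 0.124 in MYBup against mock and 0.12 in lung3 against wt, so these p-values may be too small. Across all tested genes the log2 fold changes of the 2 comparisons had a Pearson correlation of -0.137 and a Spearman rho of -0.0858, with a covariance of -0.0409. An absolute correlation as large came from 22 of 100 pairs of splits of the libraries, the real pair included.

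**Figure D3:**
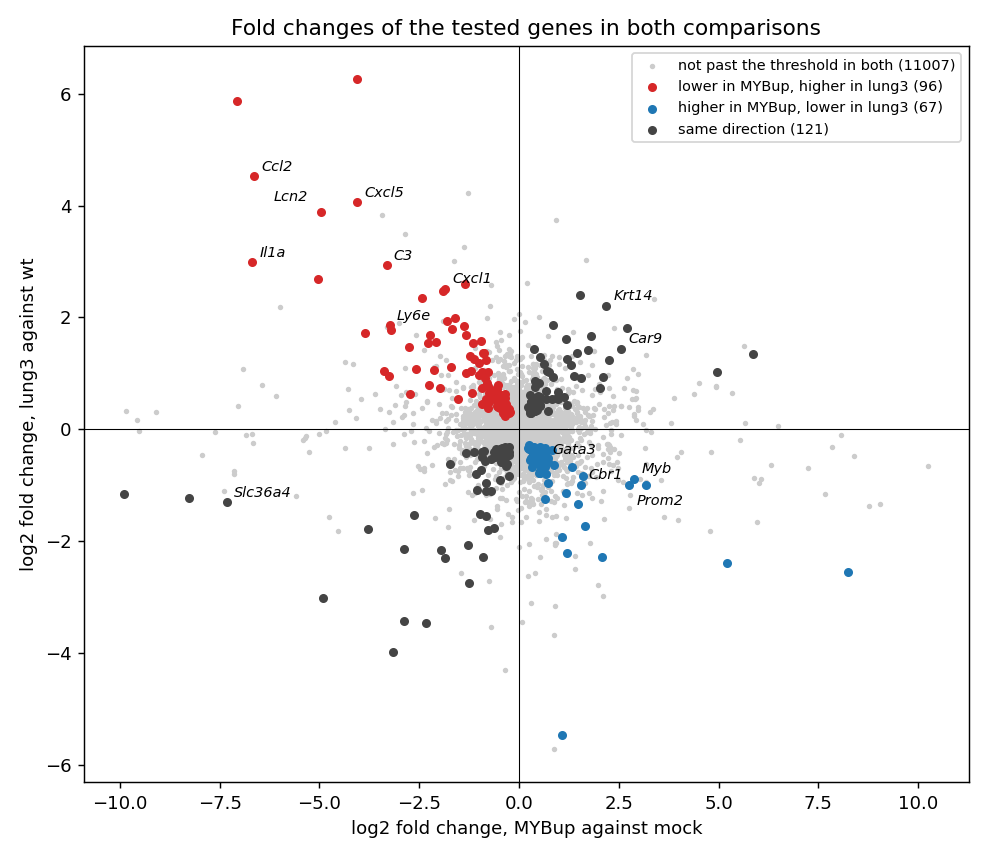
Log2 fold change of each of the 11291 tested genes in MYBup against mock (horizontal) and lung3 against wt (vertical). Coloured points passed the threshold in both comparisons, 96 lower in MYBup and higher in lung3 (red), 67 the reverse (blue) and 121 in the same direction (dark grey). Fitted values of genes with almost no counts in a group depend on the prior count.

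Mock and wt cells, the reference groups, gave the background between empty-plasmid and untransfected cells. They differed in 4056 genes, 2038 higher and 2018 lower in mock, and 637 at least 2-fold, more than MYBup and mock did. Serpine2, a protease inhibitor gene (chromosome 1, 79794197 to 79861180), was at 102 ± 45.8 CPM in mock and 4.02 ± 1.89 in wt cells (log2 fold change 4.69, SE 0.36, adjusted p = 1.99e-06). Cldn3, Pgf and Sept5 rose by 2.69, 2.48 and 2.21. Exons of Sept5 share 1902 bases with Gp1bb on the same strand, so its counts are uncertain. Rbpms, Stc2, Ly6e and Adamts1 fell by 4.35, 3.03, 2.50 and 2.28. Myb did not pass (log2 fold change 0.14, adjusted p = 0.541). Ccl2 was higher in mock (1.97, adjusted p = 0.0364), but not without mock replicate 1 or 2 or wt replicate 1 or 2 (adjusted p up to 0.114), nor with limma voom.

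Among list members, 10 of 23 epithelial genes were lower and 5 higher in mock (10 and 5 adjusted over the list alone). Rab25 had 1 count in mock and 619 in wt, a ratio of 465 (95% counting interval 83.2 to 18400), and the claudin gene Cldn7 fell by 2.62. Mesenchymal genes were higher in 5 of 12 (5 adjusted over the list alone), including Tgfbi (1.91), Foxc2 (1.17) and Twist1 (0.81). Chemokine and cytokine genes were higher in 9 of 19 and lower in 1 (9 and 1 adjusted over the list alone), including Cxcl3 (4.24) and Csf2 (2.32). S phase genes were higher in 12 and lower in 2 of 25 (12 and 2 adjusted over the list alone), including Ccne1 (0.74) and E2f1 (0.56). Cholesterol genes were lower in 9 of 21 (9 adjusted over the list alone), and matrix protease genes higher in 10 and lower in 7 of 22 (10 and 7 adjusted over the list alone), with Mmp3 up by 1.81 and Serpinb2 down (-3.67). No list was called by camera (0 of 21, with 5 at an unadjusted p under 0.05; 0 with an estimated correlation), and fry called 7. Without mock replicate 1, 2 or 3 or wt replicate 2, camera called 1, 3, 2 and 2.

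The shifts were uneven along the genome. In mock against wt cells the median log2 fold change of tested genes was -0.338 on chromosome 14 (375 genes), -0.300 on chromosome 8 (626 genes), -0.231 on chromosome 3 (543 genes) and -0.183 on chromosome 17 (561 genes), against -0.005 over all genes. On chromosome 14, 85.3% of genes had a lower value in mock. In MYBup against wt the 4 medians were -0.026, -0.033, 0.009 and 0.001, and in MYBup against mock they were 0.301, 0.255, 0.237 and 0.195. Shifts were not particular to mock cells. In MYBup against wt the medians of chromosomes 12 and 4 were 0.193 and 0.183 (0.211 and 0.106 in mock against wt), and in lung3 against wt those of chromosomes 15 and 8 were 0.182 and -0.146. Of the genes called on chromosome 14 in MYBup against mock, 168 were higher and 11 lower. With each library centred per chromosome 2359, 513 and 3374 genes were called in MYBup against mock, lung3 against wt and mock against wt.

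**Figure D4:**
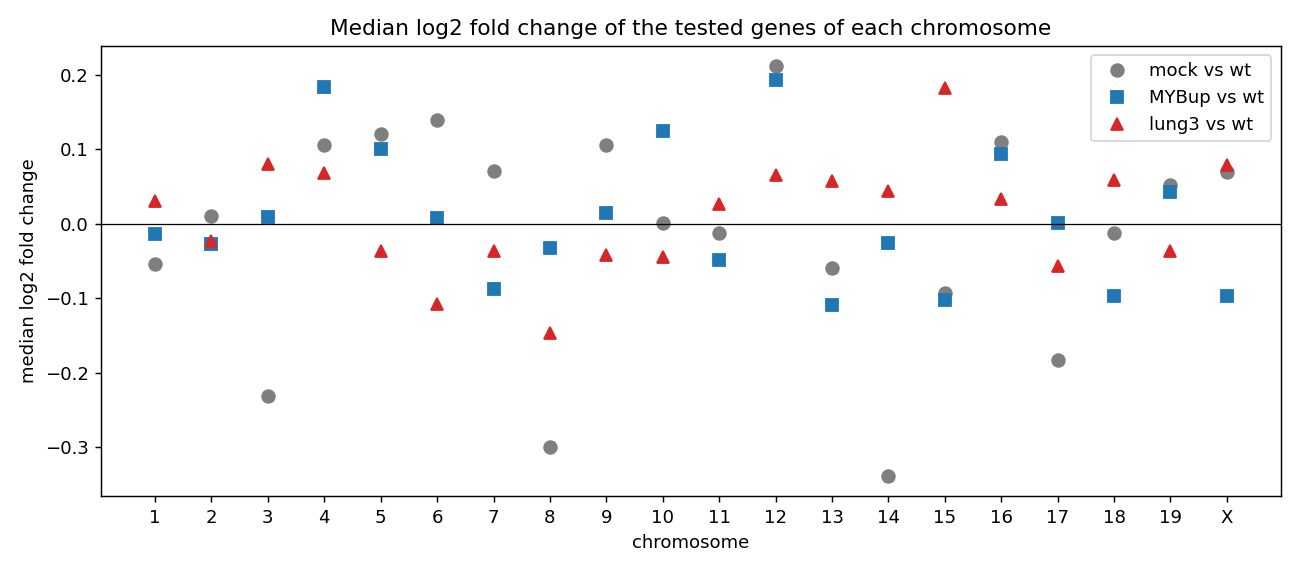
Median log2 fold change of the tested genes of each chromosome against wt, for mock (grey circles), MYBup (blue squares) and lung3 (red triangles). The mock medians of chromosomes 14, 8, 3 and 17 are -0.338, -0.300, -0.231 and -0.183, whereas those of MYBup on the same chromosomes lie between -0.033 and 0.009. The MYBup median of chromosome 12 is 0.193 and the lung3 median of chromosome 15 is 0.182.

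Most markers of host cells that a line passaged through the lung could carry were close to absent, but a few were expressed in all groups, among them Flt1 (57.0, 72.0, 50.3 and 36.9 CPM in mock, MYBup, wt and lung3), Pdgfra (40.9, 45.1, 26.6 and 18.1), Aqp5 (8.21, 12, 5.40 and 4.39) and Cd68 (4.70, 3.23, 5.20 and 7.71). Of the leukocyte, lung epithelial, endothelial and fibroblast lists 1, 2, 3 and 2 members passed the filter, and edgeR called 0 of these in MYBup against mock or lung3 against wt. Adjusted over the list alone, Cd68 was lower and Aqp5 higher in MYBup (log2 fold changes -0.55 and 0.55), and in lung3 Cd68 and Tie1 were higher and Flt1 and Pdgfra lower (0.57, 2.57, -0.44 and -0.55). Cd68 was the only tested leukocyte marker, so its p-value had no adjustment. Tie1 was near the floor, at 0.186 CPM in lung3 and 0.0298 in wt. Cd68, Aqp5 and Flt1 were named after their values were seen. The surfactant gene Sftpc had 0 counts in the 12 libraries, and the leukocyte gene Ptprc stood at 0.120 CPM in wt and 0.231 in lung3 cells. In mock against wt the endothelial marker Tie1 (73 counts against 2, ratio 48.6, 95% counting interval 13.0 to 409) and the fibroblast marker Pdgfra (log2 fold change 0.62) were higher. Postn (-2.56) was lower, but not without mock replicate 1 or 2 or wt replicate 1 or 3 (adjusted p up to 0.163). Its call also ended with DESeq2, in the fit on 6 libraries and when centred per chromosome (adjusted p up to 0.0738).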

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

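Alternatives chosen after the data were seen are centring each library per chromosome, wt in place of mock, leaving out mock replicate 3 and lung3 replicate 3 together, and the replicate blocks within lung3 and wt. Over 260 values of named genes and lists, 3832 alternative values gave 3406 on the same side of the threshold with the same direction, 405 no longer past it (247 of them with 1 library left out), 5 newly past it and 16 with the opposite direction. The losses were uneven over the comparisons. Of the named genes called in lung3 against wt, 26 of 56 lost the call without some 1 library. In MYBup against mock 20 of 98 did, and in mock against wt 21 of 87. With a 2-fold minimum 613, 164 and 637 genes were called in MYBup against mock, lung3 against wt and mock against wt. DESeq2 called 919 genes in lung3 against wt. Of genes lower in MYBup and higher in lung3, higher in MYBup and lower in lung3, and moving together, there were 34, 10 and 28 with the 2-fold minimum. Without the genes that differ between mock and wt, which leaves fewer genes, there were 38, 34 and 41. DESeq2 gave 146 and 116 for the opposite groups. The correlation of fold changes was -0.172 with an average log2 CPM of at least 3 and -0.0373 without the low-count filter. With an estimated correlation camera called 0 lists in MYBup against mock and 0 in lung3 against wt, where 2 and 5 had an unadjusted p under 0.05 and fry called 7 and 6. In mock against wt fry called 7 lists, and it does not compare a list with other genes. The replicate block on the 6 lung3 and wt libraries gave 1985 genes in lung3 against wt, and 197, 200 and 264 genes for the opposite and shared directions; within the fit of 12 libraries it gave 805 genes, and 112 genes higher in MYBup and lower in lung3. A replicate block over all 4 groups gave 2991, 565 and 3999 genes; MYBup and mock (same-number correlations -0.191, -0.496 and 0.382), and mock and wt (-0.123, 0.114 and 0.063), share only a number, not every library correlated best with its own number, and the block left 5, 7 and 0 lists. Leaving out 1 lung3 or wt library gave 237 to 688 genes in lung3 against wt, with 237 without wt replicate 1, 268 without wt replicate 2 and 294 without lung3 replicate 2; without mock replicate 2 there were 853. Leaving out any 1 of the 12 gave 37 (wt replicate 2) to 118 (wt replicate 3) genes lower in MYBup and higher in lung3, 19 (wt replicate 1) to 86 (mock replicate 3) for the reverse and 54 (wt replicate 1) to 165 (mock replicate 2) in the same direction. The correlation ranged from -0.1758 (without mock replicate 3) to -0.0978 (without lung3 replicate 1), and, without 1 library of the groups compared, the lists of lung3 against wt from 5 to 12 (12 without wt replicate 3) and those of mock against wt from 0 to 3 (3 without mock replicate 2). The log2 fold change of Myb, mock vs wt, which was not called, ranged from -0.0375 (without mock replicate 3) to 0.2572 (without mock replicate 2), and was -0.0368 without mock replicate 3 and lung3 replicate 3. Tkt in MYBup against mock was -0.002 when centred per chromosome. With wt in place of mock the log2 fold change in MYBup had the opposite sign for Stc2 (-0.7042), Tnfaip2 (0.5327), St14 (-0.3291), Tgfbi (1.0083), Nid1 (0.0557), Adamts1 (-1.6606), L1cam (-0.7725), Ccne1 (0.0971), Pfkp (-0.0437), Gclm (-0.0819), Tkt (-0.2277), Rpl15 (-0.0303) and Rps24 (-0.1435), since this alternative uses another reference group. The cause was not tested for the other changes. Genes with 0 to 3 counts in a group have folds limited by depth.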

Other observations

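Tests chosen only after the result was seen are those of splits for the correlation, of chromosome-wide shifts as the whole cause, of host leukocytes, of a single library and of replicate number 3. Some genes moved the same way in MYBup and lung3 cells. Among the 61 genes higher in both, hypoxia and glycolysis genes numbered 4 of 23 against 0.124 by chance (Fisher's exact test, one-sided, adjusted p = 0.000266), and matrix proteases and inhibitors 3 of 22 against 0.119 (adjusted p = 0.00601). The test treats genes as independent, which they are not. Its chance numbers are taken over all tested genes, although 9 of the 23 hypoxia and glycolysis genes were higher in MYBup and 4 in lung3. For the proteases and inhibitors 5 of 22 were higher in each. The test therefore counts these separate shifts again and cannot by itself show a shared response. The 4 hypoxia and glycolysis genes higher in both were Car9, P4ha2, Ndrg1 and Pfkp. Their log2 fold changes were 2.56, 0.69, 0.27 and 0.72 in MYBup and 1.44, 1.05, 0.61 and 0.32 in lung3. Against wt, the log2 fold changes in MYBup were 2.71, 1.19, 0.25 and -0.04, so Pfkp rose only against mock, where it was low. Pfkp also lost its call in lung3 when centred per chromosome (adjusted p = 0.0582) and without wt replicate 1, wt replicate 3, lung3 replicate 1 or lung3 replicate 2 (up to 0.0592). With the replicate block on the 6 lung3 and wt libraries, 264 genes moved together, against 262 for independent lists. Sfrp1 was lower in both, with log2 fold changes of -2.88 in MYBup and -2.14 in lung3. Of the 96 genes lower in MYBup and higher in lung3, 59 were also lower in MYBup than in wt, and 44 were higher in mock than in wt. Of the 67 genes of the reverse group, 47 were also higher in MYBup than in wt, and 18 were lower in mock than in wt. Cxcl16 and Lif, chemokine and cytokine genes named after their values were seen, were lower in MYBup than in mock (-3.38 and -1.17) and than in wt (-3.34 and -1.02), and higher in lung3 (1.04 and 0.65).

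The real groups gave 163 opposite genes, and 1 of 100 pairs of splits of the libraries gave as many, the real pair, with 5 as the highest of the others. For the 121 genes moving together it was 1 of 100, with 0 as the highest other. Since each other split of lung3 and wt called 0 genes, pairs with such a split could hold no shared gene, and these 2 counts say nothing on direction. A correlation of -0.1374 or larger in absolute value came from 22 of 100 pairs, up to 0.334, so chance cannot be excluded for the correlation. For the counts of genes in MYBup against mock (3038, highest other split 11), lung3 against wt (605, highest other 0) and mock against wt (4056, highest other 0), 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For the lists, 6 of 10 splits gave as many as the 5 of MYBup against mock (highest other 8) and 7 of 10 as many as the 7 of lung3 against wt (highest other 11). Though 10 splits cannot give a share under 0.05, these shares were far above it. The numbers of called lists were thus no larger than those that mixed splits gave, and chance cannot be excluded for them. In mock against wt, where the real groups gave 0 lists, the other splits gave 1 to 8.

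Of the 3038 genes changed between MYBup and mock, 981 (32.3%) differed between mock and wt but not between MYBup and wt, and 1039 (34.2%) the other way round. A difference in sequencing depth is argued against, since the share was 33.2% with all libraries thinned to 8912989 counts. Chromosome-wide shifts as the whole cause are argued against too, since 63.0% of the class kept the call in the same direction after centring per chromosome. Of the other genes 67.4% kept a call, but there the direction was not required, so the 2 shares are unlike measures. Centring by whole chromosomes does not remove shifts of parts of a chromosome. As part of the cause chromosome-wide shifts stay open, since 36.4% of the class lay on chromosomes 3, 8, 14 and 17, against 18.6% of tested genes. Calls up in MYBup against mock and down in mock against wt overlapped in 712 genes, and the reverse in 634, against 289 and 257 for independent lists; the shared mock libraries may add to this (correlation -0.472 observed and -0.506 simulated with unchanged groups; the covariance of mock was 0.227 against 0.0164 simulated), and 3 libraries cannot be split with 2 in each part. Whether transfection, selection of the mock cells or the growth of a few cells set mock apart stays open, since the design has 1 mock line.

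Chromosomes 14, 8, 3 and 17 were shifted down in mock, with 85.3%, 79.2%, 77.7% and 72.0% of their genes lower than in wt, and the chromosome 14 median was -0.349, -0.303 and -0.349 in the 3 mock libraries. GC content and gene length are argued against, since the chromosome 14 median was -0.325 after removing their trend and -0.338 before. A few regulated loci are argued against, since 4 of 4 equal parts of chromosome 14, by gene order, had a median below -0.1. Other groups were shifted too, with lung3 at -0.146 on chromosome 8 and MYBup at 0.193 on chromosome 12. A change in chromosome copy number in the mock cells is a candidate explanation, as a hypothesis only, since DNA content was not analysed here. Of the equal parts of the 4 chromosomes, 16 of 16 had negative medians in mock against wt. These chromosomes are those with the lowest medians in the same data. Negative parts were therefore likely in advance, and their number cannot decide on copy number.

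For the inflammatory genes low in MYBup and high in lung3, RNA from host leukocytes in the lung3 libraries is argued against, since the leukocyte markers other than Cd68 summed to only 0.571 CPM more in lung3 than in wt (highest, Coro1a, 0.281 CPM), while Cxcl5 alone reached 610 CPM. A single library that sets the shift of the chemokine and cytokine list is argued against, since at least 90.2% of the mean log2 fold change of its 19 tested genes (-2.098 in MYBup, 1.313 in lung3) was left without any 1 library; the number of genes lower in MYBup and higher in lung3 did depend on single libraries, with 96 in all, 41 without wt replicate 1 and 37 without wt replicate 2. Without the 4 libraries of replicate number 3, the differences in mean log2 CPM of the list were 112% and 125% of those with all libraries. They were -1.866 against -1.662 in MYBup and 1.557 against 1.248 in lung3, so the shift did not rest on that number. The number 3 libraries alone gave the smallest differences (-1.254 and 0.628), and the low values of mock and lung3 replicate 3 were seen beforehand. Leaving them out therefore cannot decide whether that number shared a day or batch. Without mock replicate 3 and lung3 replicate 3 there were 98 genes lower in MYBup and higher in lung3. An effect of the Myb level on these genes was not tested, as the design has 1 line per group, and the lower Myb call in lung3 ended without wt replicate 2, lung3 replicate 2 or lung3 replicate 3 (adjusted p up to 0.0805).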
